A study of Solanum lycopersicum with 30 samples.

How the data were processed

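Root RNA was measured on 30 Affymetrix tomato arrays, 1 per sample, in 6 groups of 5 samples that the labels call biological replicates. Per the labels' protocols, plants were moved at 8 weeks to field soil, grown for 5 weeks, and roots of the treated soil patch were taken 24 h after the injection. RNA came from a modified column method and 200 ng of it was amplified with a commercial kit, per the labels' protocols. Per the submitters' processing notes, MAS5 and Affymetrix Expression Console were used; their versions are not given in the sources used here. The values deposited by the authors are log2 MAS5 signals. Their linear form has a 2% trimmed mean of about 500 on every array, so each array was already scaled to one mean, and a shift common to all transcripts cannot be seen in them. Between 2.12% and 3.07% of probe sets per array stand at the lowest value, 0. Detection calls, scan dates and batches are not given in the sources used here, so no batch could be tested. The amounts of control RNA added are not given in them either.

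Groups, comparisons, tests, the rule for named genes, the gene lists and most of the other settings were fixed before the data were examined. The table holds 10209 probe sets, of which 108 array controls and 63 reporter controls were left out, and then the lowest 25% of the remaining 10038 by mean log2 signal over all arrays (under 5.612), which left 7528. A platform annotation, which can be old, gave 1 gene symbol for 909 probe sets (803 genes), several for 0 and none for 9129; 885 of the 909 matched a RefSeq gene table (assembly SLM_r2.1), and 207 symbols are locus numbers. No genome build is named for the values, so no coordinates are printed. Of the probe sets tested, 690 (641 genes) have a name.

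Differences were fitted on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, and eBayes with an intensity trend), with all 30 arrays in a fit of 6 group means. Each p is two-sided and was adjusted by Benjamini-Hochberg over the 7528 probe sets of its comparison, with a threshold of 0.05. The comparisons were low N and high N against water in each genotype and averaged over both, high N against low N, rmc against WT, and the difference of the N responses between genotypes. Fold changes are 2 to the power of the difference of mean log2 values. Single array measures were compared by two-sided exact permutation tests, adjusted over 40 tests. Between genotypes they were compared by permutation within treatments (100000 permutations), adjusted over 10 tests. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

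The named genes are, per comparison, the 10 largest rises and 10 largest falls among called probe sets with 1 gene name, each gene by its probe set of highest mean signal, and up to 4 called members of each list. The nitrogen and the mycorrhiza and phosphate lists add up to 4 members that did not pass. The latter list holds only PT1, PT2 and TPSI1, which are phosphate genes and not markers of mycorrhiza. Where fewer than 10 probe sets passed, the 10 named genes with the smallest p are given as values, and at most 2 unnamed probe sets per direction are named. Counts of named probe sets or calls in a comparison include those unnamed ones, unless a gene name is required in the sentence. The text gives a selection of these genes, and describes unnamed probe sets in words, with their identifiers in the figure panels where plotted.

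Of 21 lists, 17 had enough members for a set test by camera with its preset correlation of 0.01, adjusted within a comparison. Of 25 list calls over 10 comparisons, 3 held with an estimated correlation, those of the nitrogen list for high N in rmc and for low N and high N over both genotypes; fry called 19. Some members entered by a synonym alone and act elsewhere. They are bZIP1 (iron), TomloxE and a desaturase probe set of cevi19 (antioxidants), LePK4 and LePK5 (respiration), PGH1, an enolase gene (cell wall), PPCK2 (shoot) and PP2AC1 and PP2Ac2 (vascular); without them 24 calls remained, and the iron list was not called for the difference of the high N responses.

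A probe set has only a bound in a genotype where every array reads at or under the highest reading of the 23 negative-control probe sets on any array (3.365), and the bound is the ratio to that level. This rule replaced, after the data were seen, one with each array's 95th percentile, which bounded 0 probe sets; the present one bounds 1. Overlap between comparisons with shared water arrays was set against 100 simulations, and chance was examined with 100 regroupings of the arrays. The fit was tested on simulated data with 200 changed probe sets of 7528. At a 2-fold change it recovered 86% for low N in WT, 82% for high N in WT, 78.4% for low N in rmc and 86% for high N in rmc. For rmc against WT it recovered 94.8%, and for the difference of responses 66% at low N and 64.8% at high N. The simulated noise was drawn from the arrays of both genotypes together, with 5 simulations per comparison. The recovery figures therefore do not measure power in WT or rmc separately. The real arrays of a group correlated with r of at least 0.848 in rmc water and 0.956 in WT water. Of the calls in these simulations 8.07% were false for high N in WT and 6.64% for low N over both genotypes, more than the threshold of 0.05 aims at, and 3.74% or less in each other comparison.

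The settings fixed then were quantile normalization, median centring, no filter, the lowest 50% left out, log2(signal + 16), a fit of only the groups compared, robust eBayes, array weights, the replicate number as a block, and each array left out in turn. Scaling each array to its 24 poly-A spike probe sets, a covariate for the root tip and dividing cell list, leaving out 2 arrays that stand apart, and lists without members matched by synonym were added after the data were seen. Spike scaling adds one amount to every probe set of a comparison, so which falls turn positive follows from their size alone. No array was left out of the comparisons reported, and the p-values measure the spread between the samples of this one field experiment.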

Results

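Transcript levels were measured in roots of tomato (Solanum lycopersicum) on Affymetrix tomato arrays, with 30 arrays in 6 groups of 5 biological replicates. The groups cross 2 genotypes with 3 treatments of a patch of field soil. The genotypes were the wild type (WT), whose roots form mycorrhizas with soil fungi, and rmc, a mutant with reduced mycorrhizal colonization. A patch received water, a low amount of ammonium (low N) or a high amount (high N), and its roots were sampled 24 h later. The plants were 8 weeks old when moved to the field and stayed there for 5 weeks. The labels give the ammonium as 10 and 100 µM for WT but as 6.5 and 65 ppm for rmc. Read as concentrations in a solution, the labelled rmc doses are higher than the labelled WT doses of the same name. The sources used here do not say what the ppm refer to or whether a label is in error. Every comparison of the N response between genotypes carries that difference as well, and every average over both genotypes mixes these labelled doses. Between 88% and 93% of probe sets per array read above the 95th percentile of the negative controls. Correlations between arrays of a group ran from 0.848 to 0.979 across probe sets, and the number of arrays limits the precision. A gene name was available for 909 of 10038 probe sets, so most of the counts refer to unnamed probe sets.

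Among the named genes that rose in WT roots with high N, the glutamine synthetase gene gts1 rose most. By its brighter probe set it rose 4.03-fold, from a log2 signal of 9.55 ± 0.26 (SD, n = 5) in water to 11.57 ± 0.32 in high N, and all 5 high N arrays lay above the water mean (log2 difference 2.01, SE 0.32, adjusted p = 0.000751). Its other probe set rose by 1.90 (log2). The ammonium transporter gene AMT1-2 rose 2.10-fold, again on 5 of 5 arrays (log2 difference 1.07, SE 0.25, adjusted p = 0.00911). Other rises were PAP1 and Mdip1 (1.55 each), cel7 (1.14), MDHAR, a monodehydroascorbate reductase gene (1.05), the replication clamp gene PCNA (0.99) and the phosphate transporter gene PT1 (0.73). The largest named falls were TomloxE, a lipoxygenase gene (-1.33), ACO6, a gene for the ethylene-forming ACC oxidase (-1.18), PSBR (-1.15), URED (-0.87), GBF12 (-0.86) and the phytoene synthase gene PSY2 (-0.84). Of unnamed probe sets, the largest rises were 1.80 and 1.65 and the largest falls -1.90 and -1.89.

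In the nitrogen uptake and assimilation list (5 probe sets of 4 genes), 3 probe sets rose in WT with high N and 4 rose when adjusted over the list alone. The list stood above the other probe sets by limma's camera test (adjusted p = 0.000425), but not when the correlation between its members was estimated (adjusted p = 0.149 with an estimated correlation). GS2 (1.23, adjusted p = 0.0721) and the glutamate dehydrogenase gene gdh1 (0.24, adjusted p = 0.141) did not pass. Of 34 probe sets for ethylene synthesis and signalling, 6 fell, including ACO6, EIN2 (-0.49) and the receptor gene ETR2 (-0.49), and 9 fell when adjusted over the list alone. Camera placed that list lower (adjusted p = 0.0186, adjusted p = 0.669 with an estimated correlation), and its median of -0.22 became 0.12 when arrays were scaled to the poly-A spikes. That scaling shifts all probe sets alike, here by 0.338, so any smaller fall turns positive by its size alone. In the sugar and starch list, 3 of 18 probe sets rose, for the sucrose synthase genes LOC543961 (0.86) and sus3 (0.16) and the hexokinase gene hxk1 (0.45), and AGP-S2 fell (-0.34). Camera did not place that list apart (adjusted p = 0.063), whereas fry, which asks whether a list's own members move one way, called it (adjusted p = 0.0483), the phenylpropanoid and isoprenoid list (0.0483) and the nitrogen list (5.1e-05), but not the ethylene list (0.113). In the same arrays the mean of the root tip and dividing cell list differed from water by 0.516 and that of the shoot photosynthesis list by -0.511 (two-sided exact permutation p = 0.0476 and p = 0.0159; adjusted over 40 such tests, p = 0.146 and p = 0.0795). The vascular list, which holds 2 phosphatase subunit genes here, differed by 0.177, and the senescence list, which holds CYP1 alone, by -0.375 (exact permutation p = 0.0159 and adjusted p = 0.0795 for both).

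Over all 7528 probe sets tested, 1374 changed in WT with high N at an adjusted p under 0.05, of which 652 rose and 722 fell. Of 41 probe sets named for this comparison that passed, 40 moved in their direction on all 5 high N arrays, and an unnamed probe set (-1.89) on 4. The count fell to 500 without WT water replicate 3, 793 without WT water replicate 5, 902 without WT high N replicate 2, 736 without replicate 4 and 467 without replicate 5. Scaling to the poly-A spikes, chosen after the data were seen, left 9. Array weights raised the count and the root tip covariate lowered it, by the amounts given with the processing settings.

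**Figure D1:**
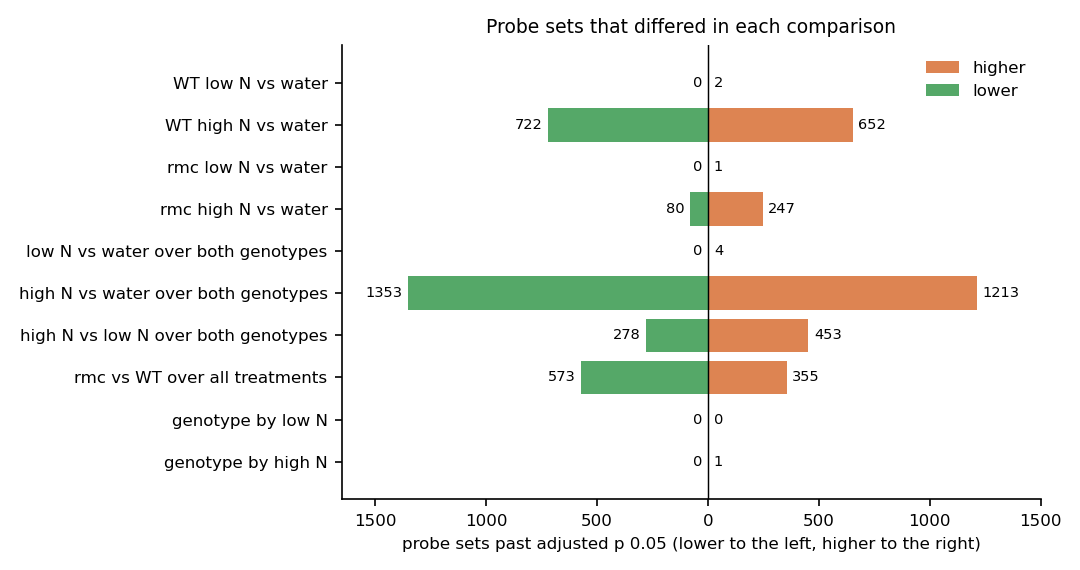
Number of probe sets that rose (up) and fell (down) in each comparison at a Benjamini-Hochberg adjusted p under 0.05, out of 7528 tested. The bars are largest for high N against water over both genotypes (1213 rose, 1353 fell), and the low N comparisons have 4 calls or fewer; with arrays scaled to the poly-A spikes, 5845 rise and 11 fall in the former.

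In rmc roots high N raised gts1, AMT1-2 and gdh1. The rise of gts1 was 7.02-fold, from 8.82 ± 0.60 to 11.63 ± 0.42 (SD, n = 5), on 5 of 5 arrays (log2 difference 2.81, SE 0.32, adjusted p = 7.33e-06), and its other probe set rose by 2.5. AMT1-2 rose 2.55-fold (1.35, SE 0.25, adjusted p = 0.00343) and gdh1 1.67-fold (0.74, SE 0.12, adjusted p = 0.00123). The largest change belonged to a probe set without a gene name, called the unnamed N-responsive probe set here, which rose 12.8-fold, from 8.16 ± 0.33 to 11.83 ± 0.35 (3.67, SE 0.30, adjusted p = 1.27e-08). The next unnamed probe set, also among the largest rises in WT, followed with 2.74. Smaller rises were ST3 (1.01), PT1 (0.92), MDHAR (0.85), the mitochondrial uncoupling protein gene UCP (0.81) and hxk1 (0.56). Falls included PSBR (-1.0), the zeaxanthin epoxidase gene ZEP (-0.73), the translation factor gene eIF-5A1 (-0.61), WRKY2 (-0.54) and WRKYIId (-0.41), and the largest falls of unnamed probe sets were -1.29 and -1.26. Of the 9 falls with a gene name that the rule selects, 1 stayed negative with poly-A spike scaling, that of PSBR, and both unnamed falls did. The scaling moved every probe set here by 0.878, so only falls larger than this stayed negative.

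The nitrogen list rose in rmc with 4 of its 5 probe sets, and 4 when adjusted over the list alone (camera adjusted p = 3.18e-08, adjusted p = 0.00746 with an estimated correlation). No other list was called by camera or fry. Of the ethylene list 1 of 34 fell, EIL2 (-0.30), a fall that turned positive with poly-A spike scaling. Against water, the means of the root tip, shoot photosynthesis, vascular and senescence lists differed by 0.227, -0.285, 0.166 and -0.338 in these arrays (exact permutation p = 0.651, 0.294, 0.0556 and 0.0635; adjusted p = 0.808, 0.511, 0.159 and 0.169). In all, 327 probe sets changed, 247 up and 80 down, against 6411 and 0 with poly-A spike scaling and 826 and 897 with array weights, and all 25 named for this comparison that passed moved in their direction on 5 of 5 arrays. This count was unsteady. It was 158, 157, 704 and 189 without rmc water replicates 1, 3, 4 and 5, and 1028, 100, 541, 164 and 52 without rmc high N replicates 1, 2, 3, 4 and 5, respectively; it was 4 when the fit held these groups alone.

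**Figure D2:**
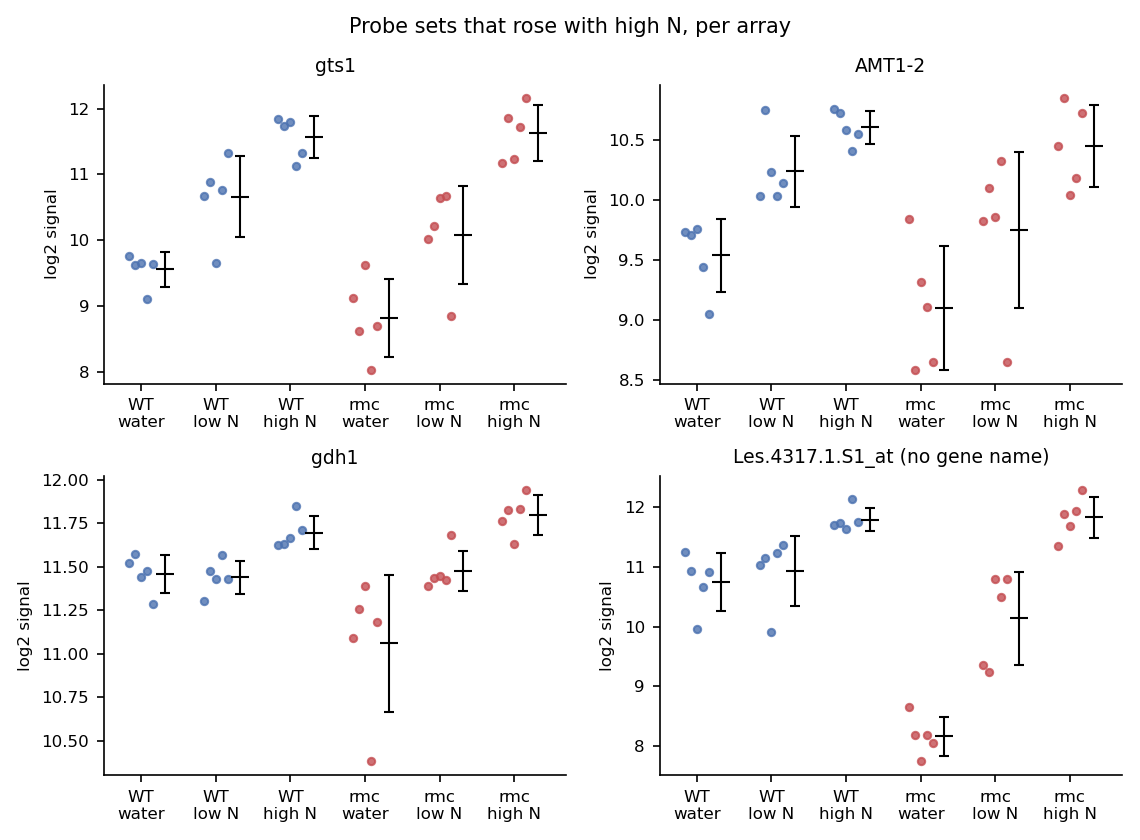
Log2 signal of gts1, AMT1-2, gdh1 and the unnamed N-responsive probe set per array by genotype and treatment, with the mean ± SD of 5 arrays. All 4 probe sets rose with high N over both genotypes; gdh1 did not pass in WT alone (log2 difference 0.24), and the unnamed probe set stands lower in rmc than in WT in water (8.16 against 10.75).

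Averaged over both genotypes, high N raised gts1 5.32-fold (2.41, SE 0.22, adjusted p = 1.29e-07) and AMT1-2 2.31-fold (1.21, SE 0.18, adjusted p = 4.36e-05), each on 10 of 10 arrays, and gdh1 1.40-fold (0.49, SE 0.08, adjusted p = 0.000175). The nitrogen list had 4 of 5 probe sets up, and 5 when adjusted over the list alone (camera adjusted p = 1.16e-05, adjusted p = 0.0437 with an estimated correlation). PAP1 (1.60), SIP (1.15), P18, a dUTPase gene (1.15), CEVI-1 (1.15), Mdip1 (1.13), LOC543878, a PR5 gene (0.97), MDHAR (0.95) and PT1 (0.82) rose too. PSBR (-1.07), ACO6 (-0.96), LOC778242 (-0.87), the auxin response gene IAA17 (-0.85), XTH5 (-0.80) and TomloxE (-0.80) fell. Here 2566 probe sets changed, 1213 up and 1353 down, or 5845 and 11 with poly-A spike scaling. Of 56 named probe sets that passed, 26 moved in their direction on all 10 arrays, and the fewest was 7, for PCNA.

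No list besides nitrogen shifted at high N over both genotypes by camera, which sets a list against the other probe sets. By fry the sugar and starch (adjusted p = 0.0143), phenylpropanoid and isoprenoid (0.0219), mycorrhiza and phosphate (0.0455), antioxidant (0.0468) and shoot photosynthesis lists (0.0468) shifted as well. Of 34 ethylene probe sets 10 fell, and 9 when adjusted over the list alone (camera adjusted p = 0.129), of which ACO6 had 3. Among 18 sugar and starch probe sets 4 rose, with LOC543961 (0.81), hxk1 (0.51) and the fructokinase gene FRK3 (0.28) among them. AGP-S2 fell (-0.32, limma adjusted p = 0.00341). In the phenylpropanoid and isoprenoid list 4 of 8 fell. They were PSY2 (-0.65), both probe sets of Psy1 (-0.58 and -0.45) and DXS (-0.34, limma adjusted p = 0.0429). These genes act in carotenoid and terpenoid synthesis, and the falls of Psy1 and DXS turned positive with poly-A spike scaling. The scaling moved every probe set here by 0.608, so a sign that turned reflects only a fall smaller than this. Of 8 auxin, gibberellin and cytokinin probe sets 3 fell, IAA17, LOC543517 (-0.66) and ARF3 (-0.41), the last not with poly-A spike scaling. The antioxidant list had 4 of 16 up, such as CEVI-1, SODCP.2 (0.47) and FESOD (0.42), both superoxide dismutase genes, and 2 down; TomloxE, one of these, entered the list by a synonym and encodes a lipoxygenase. Cell wall genes went both ways, with 3 of 30 up and 3 down, or 2 and 2 when adjusted over the list alone, cel7 (0.89) and XTH5 (-0.80) among them. Ribosomal proteins and translation factors likewise had 2 of 11 up and 3 down, or 3 and 3 when adjusted over the list alone. Of the root tip and dividing cell list PCNA (0.62) and TUB (0.62) rose and cdc2A-2 fell (-0.26), of 10 tested; that fall turned positive with poly-A spike scaling.

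Further lists held few changed members at high N over both genotypes. The iron and other metal list had 2 of 7 up, NRAMP3 (0.28) and bZIP1 (0.44), which is a transcription factor gene matched by a synonym. The mycorrhiza and phosphate list had PT1 up of 3, and 2 up when adjusted over the list alone, the pathogenesis-related list LOC543878 of 12, and 0 when adjusted over the list alone, the jasmonate and wound list COI1 down (-0.36) of 12, heat shock HSC80 down (-0.17) of 4, and shoot photosynthesis PSBR down of 3; the falls of COI1 and HSC80 turned positive with poly-A spike scaling. Of 4 aquaporin and 6 amino acid probe sets, 0 passed limma's test, and 1 and 0 had an unadjusted p under 0.05; fry gave an adjusted p = 0.561 for both. For 3 lists the median and the direction in camera differed in sign, iron (-0.07, up), aquaporins (0.08, down) and, in the mean, the ribosomal list (-0.01, up). Lists with too few members for a set test had 1 of 2 up (vascular tissue, where PP2AC1 is a phosphatase subunit gene rather than a vascular marker), 1 of 1 down (senescence, CYP1, -0.36, also positive with poly-A spike scaling), and for abscisic acid and for respiration 0 of 1 and 0 of 2 by limma, with 0 at an unadjusted p under 0.05.

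Control probe sets moved with the same treatment. The poly-A spikes, added to the RNA before amplification, read 8.58 ± 0.12 in WT water and 8.24 ± 0.20 in WT high N, and 8.94 ± 0.24 and 8.06 ± 0.57 in rmc (SD, n = 5, two-sided exact permutation p = 0.0159 in each genotype; adjusted over 40 tests, p = 0.0795). The spikes added at hybridization read 9.92 ± 0.08 and 9.90 ± 0.10 in WT, and 9.98 ± 0.10 and 9.95 ± 0.10 in rmc (exact permutation p = 0.833 and p = 0.627). The difference between the 3' and 5' GAPDH probe sets went from 0.206 to -0.118 in WT and from 0.224 to -0.144 in rmc (exact permutation p = 0.00794 each, adjusted p = 0.0795). That of actin went from 0.176 to 0.085 in WT (exact permutation p = 0.0238, adjusted p = 0.0865) and from 0.167 to 0.185 in rmc (exact permutation p = 0.651, adjusted p = 0.808). Scaling every array to its poly-A spikes moved the median of all log2 differences by 0.338 in WT, 0.878 in rmc and 0.608 over both for high N. On that scale gts1 stood 3.02 and AMT1-2 1.82 higher over both genotypes, against the median shift of 0.608. Of the 29 falls that the rule selects, 16 stayed negative, both unnamed ones included. From water to low N the GAPDH difference shifted by -0.155 in WT and -0.151 in rmc (exact permutation p = 0.0238 each, adjusted p = 0.0865). The poly-A spikes shifted by -0.158 and -0.314 (exact permutation p = 0.397 and p = 0.103).

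**Figure D3:**
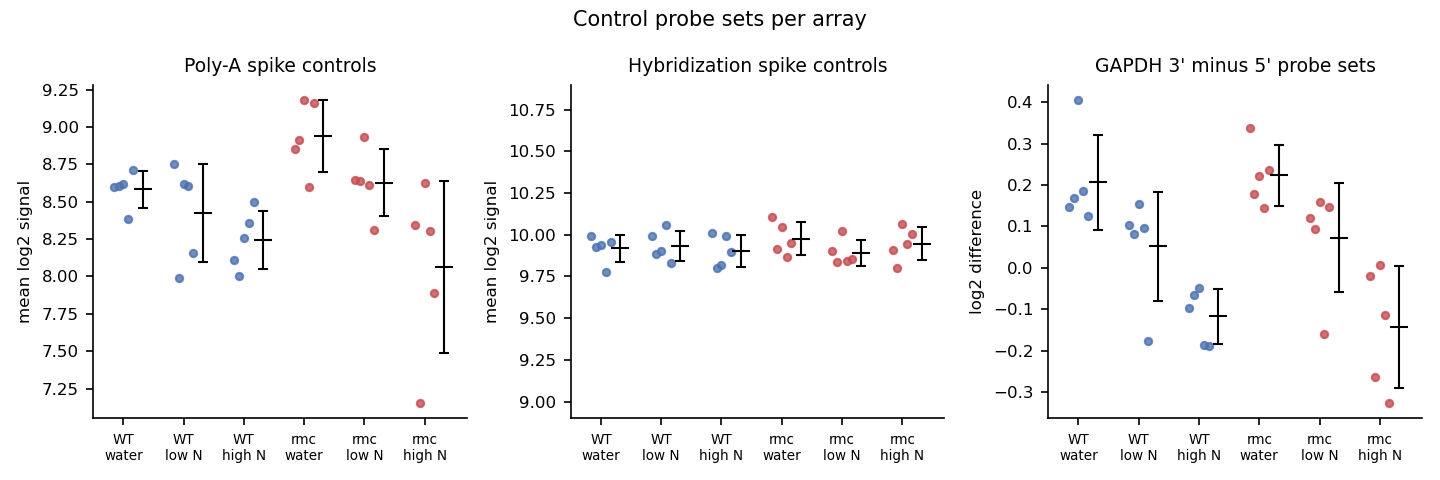
Mean log2 signal of the poly-A spikes and of the hybridization spikes, and the 3' minus 5' difference of GAPDH, per array by genotype and treatment with mean ± SD of 5 arrays. The poly-A spikes are lower in high N than in water in both genotypes (8.24 against 8.58 in WT, 8.06 against 8.94 in rmc), and the hybridization spikes lie between 9.78 and 10.11 on every array.

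Low N gave few calls. In WT roots LOC778326 rose 1.69-fold (log2 difference 0.76, SE 0.13, adjusted p = 0.0398). An unnamed probe set rose 1.5-fold (0.58, SE 0.11, adjusted p = 0.0404), and both rose on 5 of 5 arrays. Neither passed with median centring, no filter or the replicate block. In rmc roots the unnamed N-responsive probe set rose 3.94-fold (1.98, SE 0.30, adjusted p = 0.0032), also on 5 of 5 arrays. Over both genotypes 4 probe sets rose, all at an adjusted p = 0.0396, and 588 had an unadjusted p under 0.05. None of the 4 passed with quantile normalization, median centring, no filter or a fit of only the groups compared. Among them gts1 (1.18, SE 0.22) rose on 10 of 10 arrays. The unnamed N-responsive probe set (1.08), MDHAR (0.58) and LOC778326 (0.50) rose on 9 of 10. In WT alone the unnamed N-responsive probe set differed by 0.19 (SE 0.30) without passing, so most of its averaged rise came from rmc. WT low N replicate 3 read 9.906 (others 11.03 to 11.36), which lowers the WT value. Its low N response did not differ between genotypes past the threshold (limma adjusted p = 0.928). The log2 difference of AMT1-2 was 0.70 in WT and 0.65 in rmc, that of gts1 1.10 and 1.26, and that of gdh1 -0.02 and 0.41, none of which passed within a genotype. WT values that did not pass included CBF1 (2.29), XTH3 (1.91), Mdip1 (1.33), GS2 (1.04), MDHAR (0.79, adjusted p = 0.0909), PT2 (0.50) and PT1 (0.41). In rmc they included CEVI-1 (1.36), 20ox-3 (0.62), PT1 (0.43), ADC (-0.39), LHA2 (-0.28) and ACO6 (-1.05). No probe set was called down, and 435 in WT and 342 in rmc had an unadjusted p under 0.05 by limma.

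As a group the nitrogen genes stood above other probe sets at low N. In WT 0 of 5 passed limma's test over all probe sets, 4 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone (camera adjusted p = 0.000204, adjusted p = 0.115 with an estimated correlation, fry adjusted p = 0.0698). In rmc these numbers were 0, 4 and 4 (camera adjusted p = 2.4e-05, adjusted p = 0.0555 with an estimated correlation, fry adjusted p = 0.0367). Over both genotypes 1 rose, and 4 when adjusted over the list alone (adjusted p = 1.74e-07, adjusted p = 0.0121 with an estimated correlation). Camera placed 3 more lists apart in rmc at low N, none with a member that passed limma's test. All 12 pathogenesis-related and chitinase probe sets had a positive difference, with a median of 0.51 (adjusted p = 0.000173, adjusted p = 0.376 with an estimated correlation, fry adjusted p = 0.431; 2 members at an unadjusted p under 0.05). The iron and other metal list had a median of -0.24 (adjusted p = 0.0429, adjusted p = 0.11 with an estimated correlation) and the ribosomal list one of -0.07 (adjusted p = 0.028, adjusted p = 0.11 with an estimated correlation), and both medians turned positive, to 0.08 and 0.25, with poly-A spike scaling; each had 2 members at an unadjusted p under 0.05, 1 iron member was lower when adjusted over the list alone, and fry gave an adjusted p = 0.131 and p = 0.169.

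For low N in WT the count of 2 became 1 without water replicate 3 or low N replicate 3, and 0 without any other water or low N replicate (1, 2, 4 or 5). In rmc the count of 1 became 2 without low N replicate 5. Over both genotypes the count of 4 became 7 without rmc low N replicate 5, stayed at 4 without WT low N replicate 3 and was 5 without rmc water replicate 1. It became 1 without rmc water replicate 3 or 4 or rmc low N replicate 1 or 2, and 0 without any WT water replicate, WT low N replicate 1, 2, 4 or 5, rmc water replicate 2 or 5, or rmc low N replicate 3 or 4.

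Set against low N, over both genotypes, high N left gts1 2.34-fold higher (1.23, SE 0.22, adjusted p = 0.00591) and the unnamed N-responsive probe set 2.42-fold higher (1.28, SE 0.21, adjusted p = 0.00395), each on 10 of 10 arrays. Another unnamed probe set was higher by 1.33. LOC543961 (0.62), UCP (0.47), SCOA (0.42), hxk1 (0.41), PT1 (0.40) and gdh1 (0.29) were higher as well, whereas AMT1-2 (0.53, adjusted p = 0.0518) did not pass. PSBR (-0.83), PSY2 (-0.62), GBF12 (-0.55), eIF-5A1 (-0.54), ZEP (-0.46), CIF1 (-0.42) and unnamed probe sets (-1.07 and -1.03) were lower. The nitrogen list was higher with 3 of 5 probe sets, and 4 when adjusted over the list alone (camera adjusted p = 0.000663, adjusted p = 0.174 with an estimated correlation). The ethylene list was lower with 2 of 34, JERF1 (-0.26) and EIL2 (-0.18), and 0 when adjusted over the list alone (10 at an unadjusted p under 0.05, camera adjusted p = 0.0483, adjusted p = 0.713 with an estimated correlation, fry adjusted p = 0.226); its median of -0.15 became 0.22 with poly-A spike scaling, and both members turned positive. In all 731 probe sets differed, 453 higher and 278 lower, or 542 and 194 with each array centred on its median, 2234 and 2 with poly-A spike scaling and 745 and 722 with array weights; 18 of 33 named ones moved in their direction on 10 of 10 arrays, and the fewest was 8. Without 1 array the count was 261 (WT low N replicate 1), 282 (WT low N replicate 4), 458 and 268 (WT high N replicates 4 and 5), 1251 and 331 (rmc low N replicates 4 and 5), and 1659, 189, 1128 and 183 (rmc high N replicates 1, 2, 3 and 5). Without both rmc low N replicate 5 and rmc high N replicate 2, which stood apart and were chosen after the data were seen, it was 79.

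The high N responses of the genotypes ran largely in one direction. Across probe sets, which are not independent replicates, their log2 differences correlated with r = 0.738, a value that 2 of 100 relabellings of the arrays reached, and 81.6% had the same sign. Both genotypes called 197 probe sets up and 54 down, and 0 in opposite directions, where independent lists would share 21.4 and 7.67. Probe sets vary together, since relabelled arrays gave an r of up to 0.777. The shared calls were not counted under relabelling, so this excess is not set against chance. At low N r was 0.14, which 30 of 100 relabellings reached, and 52.8% had the same sign. Low N and high N within a genotype share their water arrays. Their log2 differences had a covariance of 0.0841 in WT, and of 0.0666 when the water arrays were split between them. The mean was 0.02 in 100 simulations of unchanged groups, in which both doses shared a simulated water group. A covariance of 0.0841 was reached by 3 of these. In rmc the covariance was 0.0262 against a simulated 0.0433, reached by 59 of 100, and was -0.0202 with the water arrays split. In WT 2 calls were shared between the doses, where the simulations shared 0 on average and independent lists would share 0.173. With the water arrays split 0 were shared. Each dose then had fewer water arrays, so calls could be lost for that reason alone. In rmc 1 was shared, the mean of the simulations was 1 as well, and 0 to 3 were shared with the water arrays split, against 0.0328 for independent lists.

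The comparison of rmc with WT over all treatments sets the mutant line against the wild type. Colonization was not measured here, so effects of the line and of reduced colonization are not separated. The low N and high N arrays carry the unlike dose labels here too. No probe set is named for CYCLOPS (IPD3), the gene at the rmc locus, so its transcript was not analysed here. The unnamed probe set with the largest difference read 10.53 ± 0.27 (SD, n = 15) in WT and 1.21 ± 1.00 in rmc, where all 15 arrays lay at or under the highest negative-control reading of 3.365; WT was at least 143-fold higher (adjusted p = 3.58e-20). Another unnamed probe set, which shares its identifier's stem, read 10.21 ± 0.19 in WT and 2.40 ± 0.85 in rmc, with 14 of 15 rmc arrays at or under that reading, so the size of the measured difference (-7.81) rests on signals not above background. HSP17.4, a small heat shock protein gene, was lower in rmc by 19.5-fold, at 3.97 ± 1.00 against 8.25 ± 0.99, on 15 of 15 arrays (-4.28, SE 0.36, adjusted p = 4.07e-09), with 6 of 15 rmc arrays at or under the reading. Other lower genes were LOC543717 (-3.10), the gibberellin 3-oxidase gene GA3ox1 (-2.51), LOC544264 (-1.46), MTA (-1.44), MT3 (-1.23), P69B (-1.09), ST2 (-0.92), ST1 (-0.87) and SIP (-0.86).

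**Figure D4:**
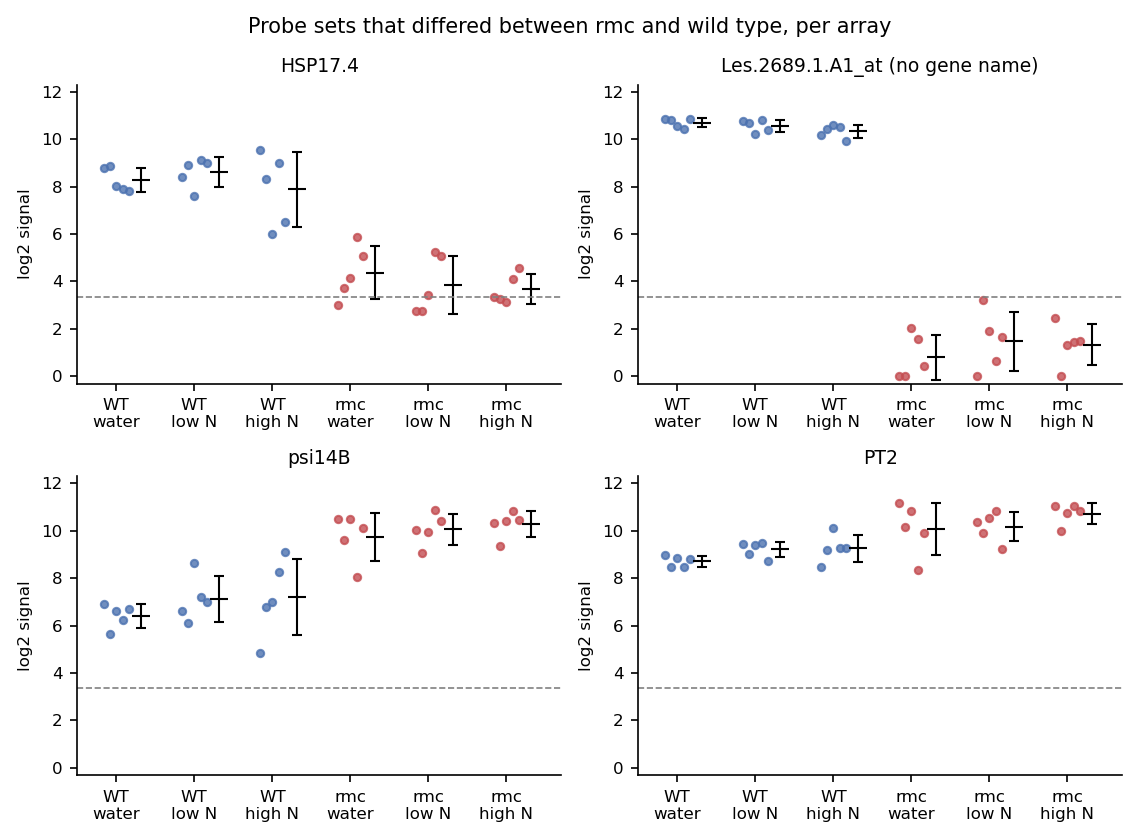
Log2 signal of HSP17.4, the unnamed probe set with the largest difference, psi14B and PT2 per array by genotype and treatment, with the mean ± SD of 5 arrays; the dashed line is the highest negative-control reading (3.365). HSP17.4 and the unnamed probe set are lower in rmc in every treatment, and psi14B and PT2 are higher.

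In rmc psi14B, named for induction by phosphate starvation, was 8.66-fold higher than in WT (3.12, SE 0.33, adjusted p = 4.05e-07) on 15 of 15 arrays, and psi14A was higher by 2.87. The phosphate transporter gene PT2 was 2.40-fold higher (1.26, SE 0.21, adjusted p = 0.00022) on 14 of 15 arrays, by 1.37 in water, 0.96 in low N and 1.46 in high N, and PT1 was higher by 0.35. rnalx, an RNase gene (1.58), ACO6 (0.96), ail (0.83), PPCK2 (0.79), NAC1 (0.76), IMP3 (0.75), PPCK1 (0.60) and SUT4 (0.50) were higher too, as were a pair of unnamed probe sets (2.74 and 2.57). The mycorrhiza and phosphate list holds the phosphate genes PT1, PT2 and TPSI1 here, and no marker of mycorrhiza. It was higher with 2 of its 3 probe sets, and 3 when adjusted over the list alone (camera adjusted p = 0.00825, adjusted p = 0.243 with an estimated correlation). TPSI1 (0.32, limma adjusted p = 0.0912) did not pass over all probe sets. The ethylene list was higher with 5 of 34 probe sets, and 7 when adjusted over the list alone, led by the 3 of ACO6 (1.26, 1.09 and 0.96), and 28 of 34 had a positive difference (camera adjusted p = 0.00235, adjusted p = 0.512 with an estimated correlation). Ribosomal proteins were lower with 3 of 11, RPL37 (-0.18), RPS25 (-0.16) and RPL3 (-0.13), and 4 when adjusted over the list alone (camera adjusted p = 0.0448, adjusted p = 0.243 with an estimated correlation). The medians of these 3 lists kept their sign under every scaling tried, quantile normalization, median centring, the offset and the poly-A spikes. Median centring and spike scaling shift all probe sets alike, by -0.00726 and -0.127 in the median. Under these the signs followed from the sizes of the medians.

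Of 16 antioxidant probe sets 4 were lower in rmc, among them SODCP.2 (-0.35), APX1 (-0.29) and CAT2 (-0.23), and 5 when adjusted over the list alone, without a shift of the list by camera (adjusted p = 0.131, fry adjusted p = 0.00954). The heat shock list had HSP17.4 lower of 4 (camera adjusted p = 0.076, fry adjusted p = 0.000456). Of 6 amino acid probe sets 0 passed limma's test over all probe sets, 3 had an unadjusted p under 0.05 and 3 were higher when adjusted over the list alone (camera adjusted p = 0.521, fry adjusted p = 0.232). The nitrogen list had 0 of 5 past the threshold in limma, 3 at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone (camera adjusted p = 0.076, fry adjusted p = 0.0176), with gts1 at -0.42 and AMT1-2 at -0.36. In the shoot photosynthesis list PPCK2, which is not specific to green tissue, was higher of 3. As a deviation from its mean over all arrays, that list averaged 0.206 ± 0.399 in rmc and -0.206 ± 0.358 in WT (SD, n = 15). The root tip and dividing cell list averaged -0.179 ± 0.652 and 0.179 ± 0.449. In a two-sided permutation test within treatments, added after the data were seen, p was 0.00338 and 0.0864 (adjusted over 10 measures, p = 0.0338 and p = 0.216). The mean of the shoot list was not tested without PPCK2, whose difference (0.79) was larger than that of PSBR (0.36). Over all, 928 probe sets differed, 355 higher and 573 lower in rmc. Of the 40 named ones 13 lay in their direction on all 15 rmc arrays, and the fewest was 11, for RPS25. With poly-A spike scaling 143 differed, 36 higher and 107 lower, and all 40 named ones kept their sign. That scaling shifts all probe sets alike, by -0.127 in the median, so only rises smaller than this shift could turn.

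Whether the N response differed between genotypes was tested directly, under the limit of the dose labels. At low N 0 probe sets passed in limma, and 184 had an unadjusted p under 0.05. At high N 1 passed, the unnamed N-responsive probe set, whose rise was larger in rmc by 2.62 (SE 0.42, adjusted p = 0.00918), and 96 had an unadjusted p under 0.05. In water it stood at 8.16 ± 0.33 in rmc and 10.75 ± 0.49 in WT (SD, n = 5), and in high N at 11.83 ± 0.35 and 11.79 ± 0.20. The difference in response was 0.80 (SE 0.45) for gts1, 0.50 (SE 0.16) for gdh1 and 0.28 (SE 0.35) for AMT1-2 at high N, and 0.16, 0.43 and -0.05 at low N, none past the threshold. The larger count of calls in WT than in rmc is therefore not shown to be a difference between the genotypes.

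Lists were placed apart in these differences by camera without a member that passed limma's test. At low N the response of rmc stood above that of WT for the pathogenesis-related list (median 0.79, adjusted p = 0.00434, adjusted p = 0.499 with an estimated correlation) and the ethylene list (0.18, adjusted p = 0.00434, adjusted p = 0.499 with an estimated correlation). It stood below for the iron and other metal list (-0.21, adjusted p = 0.0105, adjusted p = 0.0644 with an estimated correlation), the cell wall list (-0.27, adjusted p = 0.016, adjusted p = 0.499 with an estimated correlation), the root tip and dividing cell list (-0.55, adjusted p = 0.0426, adjusted p = 0.499 with an estimated correlation) and the ribosomal list (-0.10, but 0.05 with poly-A spike scaling, adjusted p = 0.013, adjusted p = 0.121 with an estimated correlation). At high N it stood above for the nitrogen list (0.50, adjusted p = 0.0415, adjusted p = 0.464 with an estimated correlation), the pathogenesis-related list (0.43, adjusted p = 0.0261, adjusted p = 0.68 with an estimated correlation) and the ethylene list (0.22, adjusted p = 0.00653, adjusted p = 0.68 with an estimated correlation). It stood below for the iron and other metal list (-0.19, but 0.35 with poly-A spike scaling, adjusted p = 0.0432, adjusted p = 0.24 with an estimated correlation), a call lost without bZIP1, its member matched by synonym (adjusted p = 0.0881). Members at an unadjusted p under 0.05 numbered 4 in the ethylene list and 1 each in the iron and cell wall lists at low N, 2 in the ethylene list and 1 in the nitrogen list at high N, and 0 in the others. Adjusted over the list alone, 1 nitrogen probe set passed at high N and 0 of any other list. The lowest fry adjusted p among these lists was 0.13 at low N and 0.803 at high N.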

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

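The test of the difference between genotypes was planned. The root tip covariate was added after the data were seen, and its test was laid down before its own result was; the other tests that weigh an explanation here were chosen after the results they bear on.

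Of 138 groups of 5 arrays over 23 measures, 13 held an array far from the others, where chance gives about 1 in 20. The 3' minus 5' difference of GAPDH was 0.406 in WT water replicate 3 (others 0.124 to 0.186), -0.177 in WT low N replicate 5 (others 0.081 to 0.154) and -0.159 in rmc low N replicate 4 (others 0.093 to 0.16). The senescence list stood at 0.2125 in WT high N replicate 1 (others -0.2658 to -0.1742). gts1 read 9.1 in WT water replicate 4 (others 9.624 to 9.753) and AMT1-2 10.75 in WT low N replicate 2 (others 10.03 to 10.23). MDHAR read 7.827 in rmc low N replicate 5 (others 8.37 to 8.519), and LOC778326 11.77 in rmc high N replicate 5 (others 11.28 to 11.39). psi14A read 2.309 in rmc water replicate 4 (others 6.989 to 8.549), and PT2 9.978 in rmc high N replicate 2 (others 10.73 to 11.03). The unnamed N-responsive probe set read 9.906 in WT low N replicate 3 (others 11.03 to 11.36) and 12.14 in WT high N replicate 4 (others 11.64 to 11.74). One of the unnamed probe sets near background in rmc read 0.07244 in rmc high N replicate 3 (others 2.024 to 2.749).

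The rise of the unnamed N-responsive probe set with high N was larger in rmc than in WT by 2.625 (log2), by the test of that difference. An unnamed probe set that shares the identifier stem of those near background in rmc lay under the signal filter and was outside the comparisons. It read 8.308 ± 0.195 in WT and 0.3643 ± 0.57 in rmc (SD, n = 15), with 15 of 15 rmc arrays at or under the highest negative-control reading (3.365), so WT was at least 30.8-fold higher (a log2 difference of at least 4.943).

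The breadth of the high N response over both genotypes, 2566 probe sets, was weighed against 3 technical explanations. A change in the share of root tips is argued against as the whole cause of the calls over both genotypes only as far as the root tip list's mean follows that share. Called members of that list went both ways (PCNA and TUB up, cdc2A-2 down), so the covariate may correct incompletely. With the list's mean as covariate, 74.2% of the calls outside that list (1901 of 2563) remained. The median size of the differences went from 0.348 to 0.279. In WT alone the covariate removed a larger share of the calls, and in rmc alone it raised the count. A common 3' bias of the RNA stays open: the GAPDH shift exceeded that of actin (larger exact permutation p of the 2 genotypes 0.0159), which was set as a bound against it, but actin moved the same way in WT (-0.0912, exact permutation p = 0.0238; 0.018 and p = 0.651 in rmc), and probe sets of different transcripts can shift unequally under one bias. Scaling of every array to one mean stays open for the falls, of which 13.2% of 1353 stayed negative when scaled to the poly-A spikes; this followed from the spike shift already known, and the amounts added are not given in the sources used here. A response of the roots to ammonium, which the design names, stays open beside it.

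The poly-A spike signal fell from water to high N in both genotypes while the spikes added at hybridization shifted by -0.0228, which argues against the scaling of the arrays as its source. The fall does not rest on rmc high N replicate 2 alone, since the shift in rmc was -0.651 without it (exact permutation p = 0.0238) and -0.878 with it. A larger share of messenger RNA in the RNA of high N roots could lower the spikes, as could a difference in the amount of spike or RNA taken, and no value here separates these.

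The 2 unnamed probe sets with the largest differences read near background in rmc. Mislabelled arrays are argued against, since 0 of 30 arrays lay in the range of the other genotype. A sequence difference of the rmc line under the probes stays open: the remaining probe set with that identifier stem was lower too (by at least 30.8-fold), and although that was set as a bound against it, a deletion across the locus would lower every one. A transcript that follows the degree of colonization also stays open. Colonization was not measured, and whether HSP17.4 follows it is not known here, so a relation to HSP17.4 cannot decide. Within WT r with HSP17.4 was 0.201 (rho 0.2, permutation p = 0.475 and 0.474, 95% interval -0.347 to 0.646, n = 15). Without the 2 farthest arrays it was 0.31, and the permutation p adjusted over 3 relations was 0.475. A difference of transcription between the genotypes, which the design names, stays open as untested.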

How the results depend on the processing

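Poly-A spike scaling, the root tip covariate and the runs without rmc low N replicate 5 and rmc high N replicate 2 together were added after the data were seen, the covariate before its own result was; the others were planned. No named gene that passed reversed its direction under the 6 planned settings run on single genes or with an array left out. Of 203 named calls, 184 held with quantile normalization, 168 with median centring, 159 without a filter, 199 with log2(signal + 16), 196 with the replicate block, 165 of 165 with the lowest 50% left out, and 2972 of 3770 values with 1 array left out (143 to 201 of 203 per array). The causes of the moves below were not tested.

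For low N in WT, 0 probe sets passed in limma with median centring, no filter, the replicate block or poly-A spike scaling (404, 532, 588 and 139 at an unadjusted p under 0.05), and 1 passed in a fit of only the groups compared. For low N in rmc that fit gave 0 (2.36% of probe sets at an unadjusted p under 0.05). For low N over both genotypes, quantile normalization, median centring, no filter and only the groups compared gave 0 (586, 634, 700 and 628 unadjusted), array weights 67, and poly-A spike scaling 2. For high N in WT, array weights gave 2757, poly-A spike scaling 9 and the root tip covariate 694. For high N in rmc, median centring gave 206, array weights 1723 (826 up, 897 down), only the groups compared 4, poly-A spike scaling 6411, all up, the root tip covariate 504, and the run without both arrays 117. For high N over both genotypes poly-A spike scaling gave 5856. For high N against low N, array weights gave 1467, only the groups compared 236, poly-A spike scaling 2236 (2234 up, 2 down), the root tip covariate 469, and the run without both arrays 79. For rmc against WT array weights gave 2151 and poly-A spike scaling 143. Of the 25 list calls 3 held with an estimated correlation. The calls shared by low N and high N in WT numbered 0 with median centring, no filter or the replicate block.

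Leaving out 1 array gave 0 to 1 for low N in WT, 467 to 1681 for high N in WT, 1 to 2 for low N in rmc, 52 to 1028 for high N in rmc, 0 to 7 for low N, 1978 to 3087 for high N and 183 to 1659 for high N against low N over both genotypes, 766 to 1250 for rmc against WT, and 0 and 1 for the differences of the low N and high N responses. Poly-A spike scaling shifted the median difference of all probe sets by 0.158 and 0.338 for low N and high N in WT, 0.313 and 0.878 in rmc, 0.236 and 0.608 over both, 0.372 for high N against low N, -0.127 for rmc against WT, and 0.155 and 0.54 for the differences of responses.

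The replicate numbers were not taken to pair the arrays, which would need every pair to exceed 0.1: same-numbered arrays correlated from -0.615 to 0.653, and 40 of 75 pairs exceeded 0.1. A weaker link is not excluded, as the mean r was 0.0911 against -0.0236 for arrays of different number, and all 5 pairs of WT and rmc high N arrays exceeded 0.1 (0.1085 to 0.4625), while 6 of 30 arrays correlated best with their own number. With the replicate number as a block, low N over both genotypes gave 2 calls (1 up, 1 down), high N in rmc 613 and high N against low N 1215; 23 list calls held, those lost being ethylene for high N against low N (adjusted p = 0.0544) and nitrogen for the difference at high N (adjusted p = 0.0779). Signal over background limits what is seen of dim transcripts: of 2510 probe sets under the filter, 174 were called in some comparison without it.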

Other observations

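The regroupings of arrays were planned before their results were seen; the relations of HSP17.4 with other probe sets were chosen after.

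Among genes of water and stress relations that the comparisons above did not describe, low N in WT left abscisic acid and dehydration genes at 0 of 1 passing in limma (0 at an unadjusted p under 0.05; log2 difference 0.45), and rmc stood 0.66 above WT for it without passing. Aquaporins had 0 of 4 passing in limma for rmc against WT, with 0 at an unadjusted p under 0.05 (median -0.09; fry adjusted p = 0.785).

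The small heat shock protein gene HSP17.4 varied between WT arrays together with 2 unnamed probe sets that are lower in rmc. A hypothesis is that these transcripts may share a source of variation between plants. After centring on treatment means, r was 0.92 with one (rho 0.886) and 0.93 with the other (rho 0.9) over 15 WT arrays, with a permutation p = 1e-05, the smallest that 100000 permutations give (adjusted p = 1.5e-05 over 3 relations). Both probe sets were picked from all those tested after their values per array had been seen, which this p does not cover, so the hypothesis stays open. Without the 2 arrays farthest from the median r was 0.957 and 0.947. Whether that source is the degree of colonization was not measured.

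Other splits of the same arrays were compared with the real one, 100 per comparison with the real one included. By the share of splits, under 5 of 100, chance can be excluded for high N in WT (1374 calls, reached by 1 split, highest other 4), high N against low N (731, reached by 1, highest other 1) and rmc against WT (928, reached by 1, highest other 70). The share was also under 5 of 100 for low N in WT (2, reached by 3, highest other 4) and low N over both genotypes (4, reached by 2, highest other 4). So it was for high N over both (2566, reached by 2, highest other 2887) and the difference at high N (1, reached by 2, highest other 2). In these comparisons another split gave as many calls or more, and the shares were not adjusted over the comparisons. Chance is therefore not excluded for them. Both low N counts were 0 with median centring or no filter, so for them the share covers the reported setting only. In limma 404 and 532 probe sets then had an unadjusted p under 0.05 for WT, and 634 and 700 over both. At 5 of 100 or more, chance stays open by the splits for low N in rmc (1 call, reached by 14, highest other 83). It also stays open for high N in rmc (327, reached by 5, highest other 2796). The same holds for the difference at low N (0, reached by 100, highest other 1). The splits with 83 and 2796 calls are several times the real counts and point to a structure of the samples, whose source was not tested. For high N in rmc, 197 rises and 54 falls were shared with WT, measured on other arrays, where independent lists would share 21.4 and 7.67. This does not settle chance, since probe sets vary together and relabelled arrays gave correlations of both responses up to 0.777. The shared calls were not counted under relabelling.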
